A study of Mus musculus with 24 samples.

How the data were processed

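Polyadenylated RNA of mouse embryonic fibroblasts was sequenced in 24 libraries, in 6 groups of 4. Per the labels' protocols, RNA was taken with TRIzol and 1 µg was made into TruSeq libraries. The deposited values are raw counts of reads per gene, whole numbers with no normalization. Per the submitters' processing notes, the authors used CASAVA, FastQC, STAR, HTSeq and DESeq2 with mouse build mm10; versions, the annotation release and the strand setting of the counting are not stated. Treatment times are not stated either.

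The files of the MSB series list 45318 genes and those of the erastin series 53379, of which 44670 are in both. Genes were matched on Ensembl identifiers without their version; symbols were found for 44585 and 53274 of them, and 79 symbols belong to more than 1 identifier. HTSeq's summary lines (reads on no gene, ambiguous or not unique) were kept out of library sizes and tests. The share of counted alignments that fell on genes was 62.15% to 69.12% in the MSB series, and is not known for MSB 20 µM replicate 1, whose file has no such lines. In the erastin series it was 40.1% to 67.49%. The file of MSB 20 µM replicate 1 has 4 columns of counts. Its last 3 columns equal replicates 2, 3 and 4 of that group at 45318 of 45318 genes, so the first column, with 33576685 counts, was taken as replicate 1.

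Each series was fitted on its own with its 12 libraries, so that the 3 dose groups share an estimate of the spread. Genes were kept by filterByExpr with its default settings, libraries were scaled by TMM, and dose groups were compared with edgeR's quasi-likelihood F-test at a Benjamini-Hochberg adjusted p under 0.05. The difference between the compounds' responses was an interaction term in a fit of all 24 libraries on the genes listed in both series. Standard errors are the log2 fold change divided by the square root of F. Levels are given as CPM, each gene's share of its library's gene counts on the usual scale. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

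The tests, the filter, the gene lists and the rule for naming genes were chosen before the data were examined. By that rule the text names the 10 genes with the largest rise and the 10 with the largest fall in each high-dose comparison, and 5 each way for low doses and dose steps. They had to pass the threshold, reach a mean of 5 CPM in a group, and have all 4 treated libraries beyond all 4 controls; predicted genes and pseudogenes were left out. The rule also names up to 4 members of each gene list with the smallest adjusted p, a member that moved the other way, and 18 fixed genes, among them Pik3c3, Slc7a11, Hmox1, Nqo1, Gpx4, Trp53 and Pten. It was applied again, after the data were seen, without a library that kept most genes from meeting it.

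Of the 30 gene lists, 24 cover stress responses, metabolism, the vesicle and lysosome systems, the cell cycle and fibroblast matrix, and 6 hold markers of other cell types. Of their members 1 could not be matched. Lists were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, adjusted over the lists of a comparison. An estimated correlation and fry, limma's rotation test of whether a list moves 1 way, were alternatives; fry does not compare a list with other genes.

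Positions come from the GENCODE annotation of the mouse build GRCm38, the same assembly as mm10. Because the strand setting is not stated, reads of genes that overlap on opposite strands cannot be told apart. Many named genes overlap another gene's exons on the opposite strand, among them Eln, Fosl1, Hmga1, Mmp12, Atf5, Becn1, Cdc45, Sqstm1, Gas6, Aifm2, Car9, Cxcl10, Dusp5, Fxyd3, Npr3, Ppp1r15a, St8sia1 and mt-Co1. A few, such as Col3a1, Spp1 and Dlg2, overlap a gene on the same strand. Prl2c2 and Prl2c3, Hspa1b, Hmga1 and the mitochondrial rRNA genes have near-identical copies, so their counts are uncertain.

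The tests of 5 comparisons were checked on simulated counts with 200 changed genes. These were drawn from the mean levels of the control libraries and the sizes of all libraries. Each gene had 1 spread for all its libraries, so no simulated library stood apart except by its size. The rates below do not cover libraries that deviate as some real ones did. The dose steps and the low-dose difference were not simulated. For MSB 20 against 0 µM, over 14580 genes, edgeR recovered 82.1%, 98.5% and 98.4% of genes changed 1.5-fold, 2-fold and 4-fold, and DESeq2, over 13978 genes, 34.3%, 56.7% and 78.8%. For MSB 10 µM, over 14601 genes, edgeR recovered 85.1%, 96.9% and 100% of them. For erastin 0.3 against 0 µM, over 14769 genes, it recovered 7.8%, 45.3% and 90.9%, and for 0.15 µM, over 14752 genes, 18.5%, 47.8% and 90.8%. For the high-dose difference between compounds, over 15090 genes, it recovered 7.6%, 41.5% and 78.5%. DESeq2 recovered 35.8%, 71.6% and 72.7% for MSB 10 µM, 20.9%, 55.2% and 92.4% for erastin 0.3 µM, 37.3%, 65.7% and 95.5% for 0.15 µM and 3%, 31.3% and 66.7% for the difference between compounds. Genes left unchanged that were called numbered 21, 15, 2, 6 and 9 by edgeR in these 5 comparisons, and 0, 0, 38, 27 and 3 by DESeq2. A list raised 1.5-fold was called in each, and of the other lists 0, 0, 1, 0 and 1 were called by camera.

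Alternatives were scaling by RLE or by library totals, no filter, a filter of 10 CPM in 4 libraries, DESeq2, only the groups compared, only genes in both series, the replicate number as a block, and leaving out each library. After the data were seen, limma voom with sample quality weights was added, as were fits without the near-empty library and without the 3 erastin libraries with the lowest share of alignments on genes. No library was left out of the main analysis. The 3 repeated columns were not analysed here.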

Results

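Gene expression was measured by RNA sequencing in mouse embryonic fibroblasts labelled as lacking p53 and PTEN. The cells were treated with menadione sodium bisulfite (MSB), a water-soluble form of the vitamin K precursor menadione that generates reactive oxygen species, at 0, 10 or 20 µM. Others received erastin, an inhibitor of the cystine transporter Slc7a11 that induces ferroptosis, at 0, 0.15 or 0.3 µM. Each of the 6 groups had 4 libraries. Total gene counts of replicates 1 to 4 were 20721054, 39861568, 34469646 and 37870173 at MSB 0 µM, and 28123091, 29623395, 35857805 and 32505531 at 10 µM. At MSB 20 µM they were 33576685, 19799, 23392805 and 27964505, so replicate 2 was nearly empty. Erastin 0 µM had 31338820, 33955680, 31044100 and 29930590, 0.15 µM had 37654797, 31994139, 30154847 and 33030197, and 0.3 µM had 33233988, 33426445, 29959999 and 24108913. Nothing says that replicates came from separate cultures, so p-values measure only the spread between these samples.

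All 24 libraries carry the same genotype label and there is no wild type among them, so the targeted genes could not be compared with an intact level. Reads were counted on Trp53 (chromosome 11, 69580359 to 69591873) and Pten (chromosome 19, 32757497 to 32826160) in every library. Trp53 was at 24.9 ± 2.02 CPM (SD, n = 4) at MSB 0 µM, 24.2 ± 0.854 at 10 µM and 38.1 ± 8.30 at 20 µM. It was at 11 ± 1.52 CPM at erastin 0 µM, 14.2 ± 4.78 at 0.15 µM and 17.9 ± 0.896 at 0.3 µM. Pten was at 42.0 to 50.5 CPM across the MSB libraries and at 34.6 to 81.0 across the erastin libraries. The near-empty library held 1 count of each gene. Counts per gene do not separate a deleted exon from the rest of a transcript, so these levels check the labels neither way.

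Replicates were alike in the untreated groups and in MSB 10 µM, with Spearman correlations across genes of at least 0.995. The lowest pair was at 0.932 in erastin 0.15 µM, 0.961 in erastin 0.3 µM and 0.74 in MSB 20 µM. In erastin, the first principal component held 57.6% of the variance. Replicate 4 of 0.15 µM lay at 91.7 on it, beyond the 0.3 µM libraries at 31.1 to 52.1 and far from replicates 1 to 3 of its own group at -33.8 to -31.0. Replicates 2 and 4 of 0.3 µM had 56.51% and 40.1% of counted alignments on genes and replicate 4 of 0.15 µM 60.39%, against at least 65.8% in the other erastin libraries. These 3 libraries are called low-yield below. Fits without them, chosen after the data were seen, keep only replicates 1 and 3 at 0.3 µM. Such fits leave out the spread that these deviating libraries add, so their small p-values and larger counts rest on few libraries.

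The first comparison asked what a high dose of MSB changes. MSB at 20 µM raised oxidative stress genes such as Nqo1 and Hmox1, the prostaglandin synthase gene Ptgs2, immediate early genes and genes of the cell cycle. It lowered Eln, most of the matrix genes tested, all the cholesterol synthesis genes tested, and the mitochondrially encoded mRNAs that were tested. By edgeR, 9792 of 14842 genes passed the threshold, 4852 higher and 4940 lower, and 1575 of them changed at least 2-fold. Without the near-empty library edgeR called 9957 genes, but DESeq2 called 3205 with it and 9485 without it. Scaled by library totals, 62.4% of the called genes were higher, against 49.6% under TMM, and the median of all genes moved from 0.00 to 0.12.

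Ptgs2 (ENSMUSG00000032487; chromosome 1, 150100031 to 150108227) rose with MSB at 20 µM by 3.76 ± 0.05 on the log2 scale (SE; adjusted p = 2.55e-20), from 29.4 ± 1.28 CPM (SD) to 488 ± 113. Without the near-empty library, which held 13 of its counts, the treated mean was 432 ± 12.8. Grem1 rose by 3.52 ± 0.07 and Vnn1 by 3.13 ± 0.09. F2rl1, Foxq1, Fam71f1, Fosl1 and Hmga1 rose by 2.04 to 2.45. Angptl7 fell by 6.97 ± 0.14 (adjusted p = 2.35e-17) and Eln (ENSMUSG00000029675; chromosome 5, 134702593 to 134747323) fell by 5.94 ± 0.11 (adjusted p = 7.84e-18). Eln went from 50.4 ± 3.50 CPM to 0.642 ± 0.480, with 0 counts in the near-empty library, which could not show a level this low. Megf6, Spock2, Fxyd3, Fam84a, Fmo2, Cybrd1, Sez6l and Cldn15 changed by -4.64 to -3.78. Chosen again without the near-empty library, the genes also included Acsbg1 at 4.02 ± 0.215 (adjusted p = 1.29e-10), Mmp10 at 2.81 ± 0.11, Ereg at 2.60 ± 0.13 and St8sia1 at -5.32 ± 0.17 (adjusted p = 2.58e-13). They included Slc14a1 as well (adjusted p = 1.25e-11), which the filter had left out of the fit of all libraries, with 5.13 to 6.29 CPM in the treated libraries and at most 1 count in a control.

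Of 32 tested NRF2 targets, 28 rose with MSB at 20 µM, 3 fell and 1 did not pass, the same numbers as when adjusted over the list alone. Nqo1 (chromosome 8, 107388225 to 107403206) rose by 2.35 ± 0.07 (adjusted p = 7.91e-16), from 8.25 ± 0.371 CPM to 45.8 ± 1.93 without the near-empty library, in which it had 0 counts. Esd rose by 1.81, Hmox1 by 0.97 and Txnrd1 by 0.84, while Aox1 fell by 0.62. The list stood above other genes by camera (adjusted p = 2.13e-10), with adjusted p = 0.116 with an estimated correlation. Of 26 immediate early and AP-1 genes 22 rose and 1 fell (median 0.98; camera adjusted p = 2.13e-10, and 0.116 with an estimated correlation), among them Fosl1, Dusp6 and Myc, with Dusp5 at -0.28. Of 39 ATF4 and amino acid response genes 27 rose and 6 fell, with Ppp1r15a at 1.59, Cth at 1.19, Atf3 at 1.14 and Atf5 at -1.01 (adjusted p = 7.38e-07; 0.207 with an estimated correlation). Of 20 aminoacyl-tRNA synthetases 19 rose, and 20 when adjusted over the list alone, with Wars at 1.08 (adjusted p = 1.01e-07; 0.116 with an estimated correlation).

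Of 30 G2/M genes 29 rose with MSB at 20 µM (median 0.64; camera adjusted p = 1.57e-17), and this was the only list still past the threshold with an estimated correlation (adjusted p = 0.0211), but not without the near-empty library (0.078). Bub1 rose by 1.05 and Aurkb by 1.00. Of 33 S phase genes 32 rose, with Mcm10 at 1.45 and Cdc45 at 1.30 (adjusted p = 1.78e-10; 0.207 with an estimated correlation). Of 54 ribosomal protein genes 51 rose (median 0.36; adjusted p = 1.35e-15; 0.238 with an estimated correlation). Of 46 nuclear oxidative phosphorylation genes 26 rose and 1 fell, and 26 and 0 when adjusted over the list alone (adjusted p = 0.000546; 0.459 with an estimated correlation).

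All 25 cholesterol synthesis genes fell with MSB at 20 µM (median -0.98; camera adjusted p = 4.09e-10; 0.116 with an estimated correlation). Insig1 fell by 1.56, Dhcr24 by 1.51 and Hmgcs1 by 1.43. Of 35 matrix genes 29 fell and 5 rose (median -0.73; adjusted p = 8.69e-12; 0.207 with an estimated correlation). Col6a1 fell by 2.29, Col3a1 by 1.80 and Col1a2 by 1.79, while Ccn2 rose by 1.28. Of 13 mitochondrially encoded mRNAs 7 were tested, and all of these fell, mt-Cytb by 1.78 and mt-Co1 by 1.73. Their median was -1.47 (camera adjusted p = 4.19e-08, 0.116 with an estimated correlation, and 0.000398 without the near-empty library). Without the near-empty library 8 were tested and 7 fell, while mt-Nd3 did not pass (-0.69, edgeR adjusted p = 0.181). The mitochondrial rRNA genes went the other way: mt-Rnr1 (chromosome M, 70 to 1024) rose by 2.64 ± 0.15 (adjusted p = 1.55e-11), from 135 ± 28.3 CPM to 929 ± 114, and mt-Rnr2 rose by 2.49 ± 0.15 (adjusted p = 3.18e-11). Without MSB, mt-Rnr1 was also high in 2 of the 3 low-yield libraries, at 3770 CPM in replicate 4 of erastin 0.15 µM and 929 CPM in replicate 4 of 0.3 µM. The other erastin libraries, the low-yield replicate 2 of 0.3 µM among them, were at 136 to 324 CPM. Of 27 unfolded protein response genes 18 fell, such as Calr by 0.99, and 2 rose, such as Atf6 by 0.40. Camera's adjusted p was 0.00712, 0.464 with an estimated correlation and 0.000736 without the near-empty library.

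The study concerns the lipid kinase VPS34, encoded by Pik3c3. With MSB at 20 µM, Pik3c3 changed by 0.09 ± 0.05 (adjusted p = 0.158) and its partner Pik3r4 by -0.01 ± 0.05 (adjusted p = 0.858), neither past the threshold; Becn1 rose by 0.28 and Atg14 by 0.41. Of 50 genes of VPS34 complexes and phosphoinositide machinery 22 rose and 9 fell, with Mtm1 at 0.64 and Uvrag at -0.48 (camera adjusted p = 0.857). Of 40 autophagy genes 12 rose and 16 fell, and 13 and 16 when adjusted over the list alone (adjusted p = 0.91), with Sqstm1 at 0.60 and Gabarapl1 at -0.66. Of 56 lysosome genes 14 rose and 25 fell (adjusted p = 0.274), with Gpnmb at 1.79 and Tfeb at -1.13. Of 11 vitamin K cycle genes 3 rose and 5 fell (adjusted p = 0.382), Gas6 by -2.75 and Ggcx by -1.02, while Ubiad1, Vkorc1l1 and Aifm2 did not pass. Slc7a11 rose by 0.52, Chac1 by 0.56, Tfrc by 0.46 and Gpx4 by 0.25.

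The other lists with MSB at 20 µM were mixed. Of 34 ferroptosis regulators 16 rose and 12 fell (adjusted p = 0.149), of 29 hypoxia and glycolysis genes 8 and 17 (0.212), and of 31 interferon response genes 7 and 9 (0.793). Of 41 glutathione and thioredoxin genes 22 rose and 12 fell (0.00712; 0.464 with an estimated correlation, and 0.111 without the near-empty library). Of 24 heat shock genes 14 rose and 5 fell (0.00712; 0.31 with an estimated correlation, and 0.0238 without the near-empty library). Of 28 p53 target genes 14 rose and 8 fell (0.00718; 0.116 with an estimated correlation, and 0.151 without the near-empty library). Of 22 inflammatory genes 10 rose and 5 fell (9.42e-05; 0.116 with an estimated correlation), with Cxcl1 at 1.5 and Saa3 at -1.54. Without the near-empty library, camera's adjusted p for the inflammatory list was 0.0424, and 0.387 with an estimated correlation. Of 5 metallothionein and zinc genes 1 rose and 3 fell (0.084). Among markers of other cells, 3 of 5 macrophage genes rose, although camera placed this list below other genes (adjusted p = 0.953) and its median was 0.64. Without the near-empty library camera placed the list above other genes (adjusted p = 0.224, median 0.65), so the downward direction came with that library. For the epithelial list 1 of 7 rose and 6 fell, for the neural list 2 of 5 and 2, for the endothelial list 1 of 4 and 1, for the muscle list 0 of 4 and 2, and for the adipocyte list 1 of 2 and 1.

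**Figure D1:**
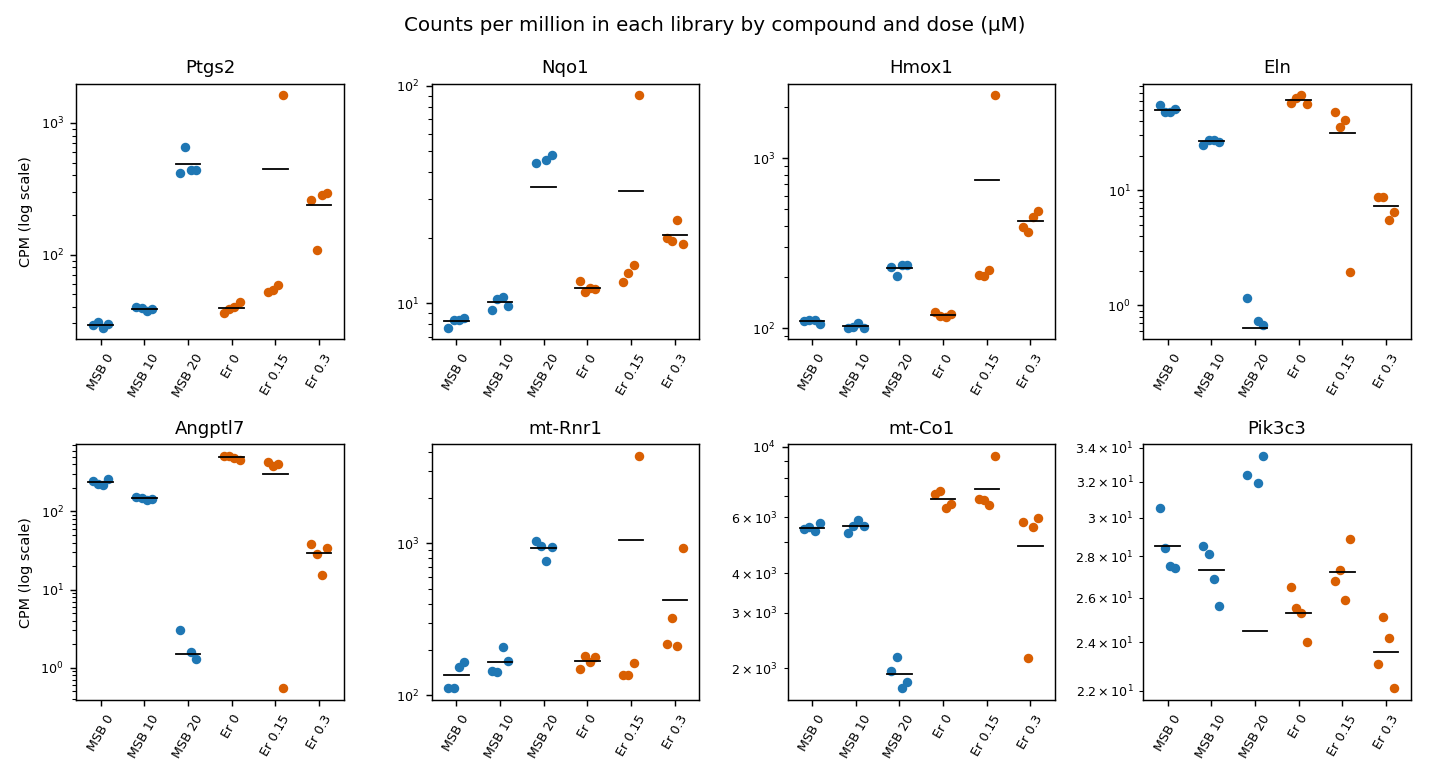
CPM of named genes in each library (points, log scale) by dose of MSB or erastin in µM, with the mean of each group as a bar. Libraries with 0 counts are not drawn, as the near-empty replicate 2 of MSB 20 µM for Eln, but the means include them; replicate 4 of erastin 0.15 µM stands apart from its group, with Ptgs2 at 1620 CPM.

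The low dose of MSB was compared with its controls to ask whether it moved the same genes. MSB at 10 µM raised most G2/M genes tested slightly and lowered most cholesterol synthesis genes. Of 14842 genes 1334 passed by edgeR, 708 higher and 626 lower, and 14 changed at least 2-fold. This count was not stable to the choice of libraries: it was 690 without MSB 0 µM replicate 4, 715 without replicate 2, 795 without replicate 1, 821 without MSB 10 µM replicate 2 and 1842 without MSB 0 µM replicate 3. DESeq2 called 5 genes, and 1673 without the near-empty library of the high dose. The largest changes were Apln at 0.91 ± 0.12 (adjusted p = 0.000201), Calca at 0.78, Arrdc3 at 0.71, Npr3 at 0.69 and Fos at 0.62, and falls of Eln by 0.92 ± 0.06 (adjusted p = 8.04e-08), Cxcl14 by 0.75, Angptl7 by 0.69, Rasgrp3 by 0.62 and Cybrd1 by 0.61. Ptgs2 rose by 0.39 and Nqo1 by 0.28, while Hmox1 changed by -0.10 (adjusted p = 0.124).

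Of 30 G2/M genes 28 rose with MSB at 10 µM, and 29 when adjusted over the list alone (median 0.28; camera adjusted p = 1.43e-44, and 0.000626 with an estimated correlation). Of 25 cholesterol synthesis genes 20 fell, and 22 when adjusted over the list alone (median -0.23; adjusted p = 1.18e-15; 0.111 with an estimated correlation). Of 33 S phase genes 21 rose, and 29 over the list alone (adjusted p = 1.78e-09; 0.341 with an estimated correlation). Of 54 ribosomal protein genes 18 rose, and 46 over the list alone (adjusted p = 2.72e-40; 0.121 with an estimated correlation). Of 29 hypoxia genes 18 rose (adjusted p = 1.16e-15; 0.121 with an estimated correlation), whereas from 10 to 20 µM 7 of them rose and 19 fell (adjusted p = 0.00379; 0.514 with an estimated correlation). Of 56 lysosome genes 12 fell (adjusted p = 1.07e-05; 0.544 with an estimated correlation).

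From 10 to 20 µM of MSB, edgeR called 9201 genes, 4555 higher and 4646 lower, and DESeq2 2519, or 8837 without the near-empty library. Under library totals 63.5% were higher, against 49.5% under TMM. Ptgs2 and Grem1 each rose by 3.37, and Angptl7 fell by 6.27 and Eln by 5.02. Without the near-empty library Acsbg1 rose by 3.90 and Ereg by 2.65, and St8sia1 fell by 5.07. Across 14842 genes, which are not independent replicates, the fold changes of the 2 doses against the same controls correlated with r = 0.48. Unchanged groups simulated against those controls gave a mean r of 0.455, and with the controls split between the comparisons r was 0.362. The covariance was 0.0648, against 0.00984 simulated, a difference of 0.0549. With the near-empty library left out, r was 0.476 and the simulated mean 0.444, with a highest simulated r of 0.485, and the covariance was 0.0725 against 0.0119. Of the genes called at both doses, 583 were higher in both, where independent lists would share 231.5, and 573 lower in both, against 208.4. These expected numbers leave out that both doses share their controls, so the excess is not a measure of a shared effect.

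Erastin at 0.3 µM was compared with its controls for the response to a known inducer of ferroptosis. Erastin raised matrix metalloproteinase genes (Mmp12, Mmp10), some inflammatory genes (Il6, Cxcl1, Ccl2) and some heat shock genes, and lowered most cholesterol synthesis genes and some hypoxia genes. By edgeR, 3901 of 15124 genes passed, 1961 higher and 1940 lower, and 1483 changed at least 2-fold. More passed without the low-yield libraries: 9511 genes without all 3, and 6929 without replicate 4 of 0.15 µM in the spread. Leaving out an erastin 0 µM library lowered the count to 2450, 2322, 2319 and 2333 for replicates 1 to 4. Under library totals 37.2% of called genes were higher, against 50.3% under TMM.

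With erastin at 0.3 µM, Prl2c3 rose by 6.34 ± 1.89 on the log2 scale (adjusted p = 0.0288) and Mmp12 (ENSMUSG00000049723; chromosome 9, 7344381 to 7369499) by 5.92 ± 1.5 (adjusted p = 0.0147), from 0.514 ± 0.0754 CPM to 29.6 ± 7.04. Without the low-yield libraries Mmp12 rose by 6.04 ± 0.17 (adjusted p = 4.85e-17). Prl2c2 rose by 5.43, Mmp10 by 4.89, Acsbg1 by 4.66, Il1rl1 by 3.55, Ngf by 3.13, Wincr1 by 3.06, Spp1 by 3.00 and Fosl1 by 2.81. Cybrd1 (chromosome 2, 71117923 to 71142926) fell by 4.50 ± 0.67 (adjusted p = 0.00147), from 32.7 ± 2.59 CPM to 1.36 ± 0.301. Esr1, Angptl7, Fmo2, Lrrtm1, Kbtbd11, Slitrk4, Col14a1, Megf6 and Zbtb8b changed by -4.27 to -3.51.

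Ptgs2 and Hmox1 rose by 2.65 (adjusted p = 0.0687) and 1.91 (0.0605) with erastin at 0.3 µM and did not pass. Without the low-yield libraries, which leaves replicates 1 and 3 at 0.3 µM, they rose by 2.82 ± 0.06 (adjusted p = 5.55e-18) and 1.84 ± 0.06 (adjusted p = 3.19e-16). Nqo1 (0.88; adjusted p = 0.23) and Slc7a11 (0.69; 0.308) did not pass either, and rose by 0.92 and 0.87 without these libraries (adjusted p = 5.98e-09 and 4.48e-09). Gpx4 changed by 0.13 (0.686) and, without them, by -0.29 (0.00219). Chac1 changed by -0.23 (0.416) and, without them, by -0.33 (0.00101). With all libraries Pik3c3 changed by -0.01 (0.942), Pik3r4 by -0.46 (0.0299), Aifm2 by -0.50 (0.0355) and Trp53 by 0.79 (0.012).

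Of 25 cholesterol synthesis genes 22 fell with erastin at 0.3 µM, 24 when adjusted over the list alone and 25 without the low-yield libraries (median -1.22; camera adjusted p = 5.56e-09; 0.649 with an estimated correlation), among them Lss and Dhcr7. Of 24 heat shock genes 11 rose, 16 over the list alone and 24 without the low-yield libraries (7.3e-07; 0.649 with an estimated correlation). Of 33 NRF2 targets 13 rose, 19 over the list alone (4.41e-06; 0.649 with an estimated correlation), with Txn1 at 1.19 and Gsta4 at 1.11. Of 26 immediate early genes 9 rose (6.01e-06; 0.649 with an estimated correlation) and of 29 hypoxia genes 13 fell (1.73e-06; 0.167 with an estimated correlation), Car9 by 2.41. The S phase list, with 17 of 33 higher (7.61e-07), and the inflammatory list, with 10 of 23 higher and 1 lower (1.33e-05), were past the threshold with an estimated correlation (adjusted p = 0.0174 for both), but not without the low-yield libraries (0.08 and 0.135). With the low-yield libraries left out, 26 of 32 NRF2 targets, 23 immediate early, 27 S phase and 16 inflammatory genes rose, and 25 hypoxia genes fell. Il6 rose by 2.55 and Cxcl1 by 1.74.

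Of 54 ribosomal protein genes 5 rose with erastin at 0.3 µM (median 0.59; camera adjusted p = 1.73e-06; 0.793 with an estimated correlation), but without the low-yield libraries their median was 0.01 (adjusted p = 0.607). Of 46 nuclear oxidative phosphorylation genes 1 rose (median 0.36; adjusted p = 0.0165; 0.84 with an estimated correlation). Without these libraries 3 rose and 28 fell (median -0.17; adjusted p = 0.0335; 0.831 with an estimated correlation). Of 39 ATF4 genes 2 rose and 7 fell (adjusted p = 0.671), with a median of 0.08 where camera pointed down. The matrix list had 7 of 35 higher and 8 lower (0.321), the autophagy list 1 of 40 higher and 10 lower (0.321) and the VPS34 list 2 of 50 higher and 5 lower (0.46). With the low-yield libraries left out, 13 were higher and 17 lower for ATF4, 13 and 19 for matrix, 13 and 16 for autophagy and 18 and 12 for VPS34, and none of these lists passed by camera.

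**Figure D2:**
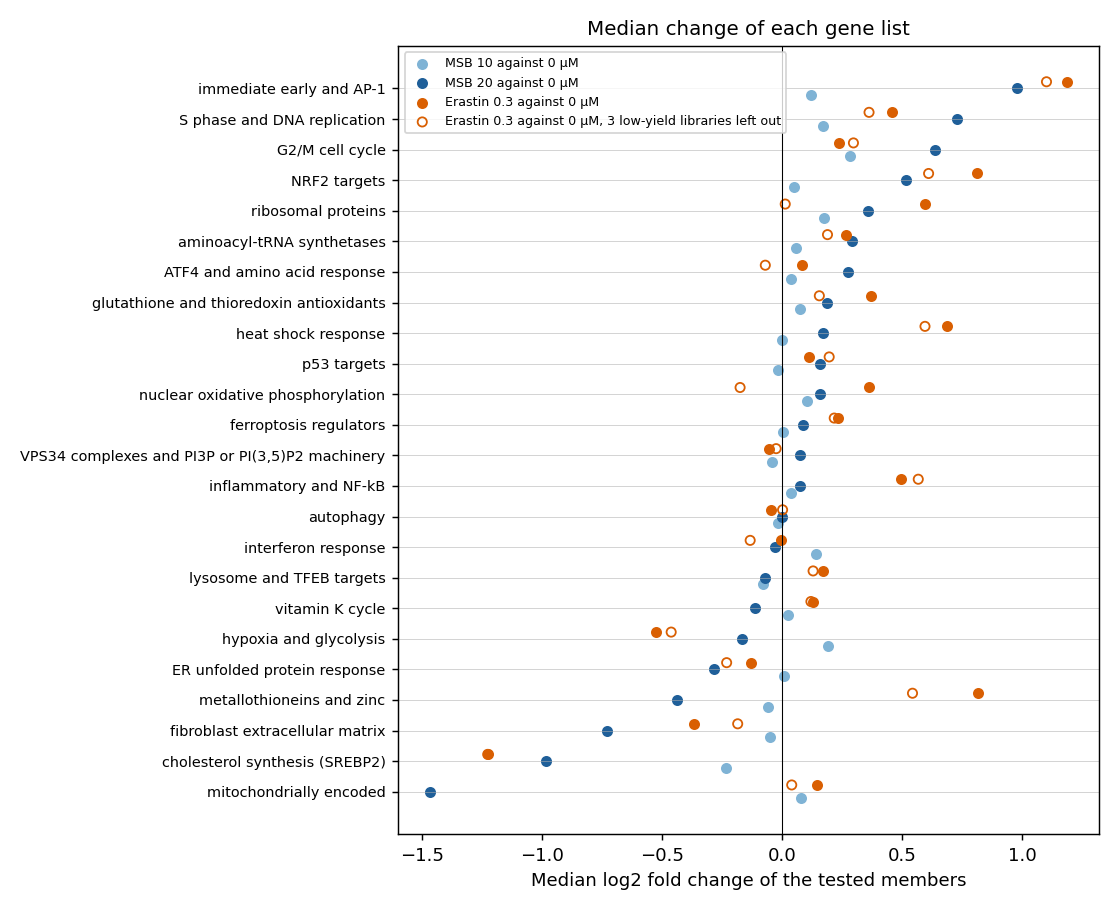
Median log2 fold change of the tested members of each gene list (x axis) for MSB at 10 and 20 µM and erastin at 0.3 µM, each against its 0 µM group; open circles leave out the 3 low-yield libraries. The cholesterol synthesis list lay at -0.98 with MSB at 20 µM and -1.22 with erastin, and the ribosomal protein list went from 0.59 to 0.01 without the low-yield libraries.

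With erastin at 0.15 µM, edgeR called 0 of 15124 genes; 823 had an unadjusted p under 0.05, DESeq2 called 2 and limma voom with quality weights 224. Replicate 4 stood far from the others of this group: its levels were 2340 CPM for Hmox1 and 1620 CPM for Ptgs2, against 204 to 219 and 51.7 to 58.4 CPM in replicates 1 to 3. Leaving it out alone gave 2 genes, and leaving out all 3 low-yield libraries gave 358, 159 higher and 199 lower. Without them the largest changes were Tnip3 at 1.11 ± 0.14 (adjusted p = 7.55e-05), Hspa1b at 0.86, Hmox1 at 0.81 ± 0.05 (adjusted p = 1.46e-08), Il1rl1 at 0.73 and Ddx4 at 0.72, and falls of Lrrtm1 by 0.70, Cxcl14 by 0.68, Nxph3 by 0.67, Aqp1 by 0.63 and Parvb by 0.61. Of the 32 NRF2 targets tested in that fit 13 rose, against 0 of 33 with all libraries, where edgeR called 0 genes.

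From 0.15 to 0.3 µM of erastin, edgeR called 1337 genes, 618 higher and 719 lower. Without the low-yield libraries it called 8489, and 29 when only these 2 groups were fitted. Leaving out replicates 1, 2, 3 and 4 of 0.15 µM gave 343, 266, 306 and 5472 genes, and replicate 4 of 0.3 µM gave 553. Under library totals 31.6% of called genes were higher, against 46.2% under TMM, and the median of all genes moved from -0.04 to -0.13. Ddx4 rose by 2.17 ± 0.25 (adjusted p = 0.00141), Il6 by 1.84, Cxcl10 by 1.73, Ccl7 by 1.66 and Ifit1 by 1.60, and Parvb fell by 2.31 ± 0.22 (adjusted p = 0.000578), Stc1 by 2.10, Lpin1 by 1.77, Trp53inp1 by 1.73 and Ndrg2 by 1.62. Without the low-yield libraries the genes chosen were Mmp12 at 5.05, Prl2c3 at 4.89, Mmp10 at 4.08, Prl2c2 at 4.04 and Acsbg1 at 3.55, and Angptl7 at -3.89, Cybrd1 at -3.78, Esr1 at -3.49, Zbtb8b at -3.48 and Fmo2 at -3.36. With all libraries the first 5 did not pass, Mmp12 at 0.44 (adjusted p = 0.826) and Prl2c2 at 0.24 (0.902), and the others in the opposite direction, Prl2c3 at -0.84 (0.704), Mmp10 at -1.04 (0.612) and Acsbg1 at -0.56 (0.759). Neither did Angptl7 (0.0663) and Fmo2 (0.0516). Fold changes of the 2 doses against the same controls correlated with r = 0.703 across 15124 genes and r = 0.55 without the low-yield libraries. Simulated unchanged groups gave 0.502 and 0.38, and split controls 0.65 and 0.401. The covariance was 0.266 against 0.0519 simulated, and 0.0855 against 0.0131 without the low-yield libraries.

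The compounds were compared to ask whether their high-dose responses were alike. Across 14058 genes the fold changes of MSB 20 µM and erastin 0.3 µM, which have separate controls, correlated with r = 0.698 (rho = 0.644). Both raised 1507 genes, where independent lists would share 636.7, both lowered 1432, against 631.4, and 184 went opposite ways, against 1268.6. Without the 4 doubted libraries, which are the near-empty library and the low-yield libraries, both raised 2978 (1544.8), both lowered 3087 (1544.5) and 902 went opposite ways (3089.4). The response itself differed at 1360 of 15569 genes by the interaction term, 595 with a higher and 765 with a lower log2 value for MSB. The doses of the compounds were not matched, the series were separate and treatment times are not stated. A difference in dose strength, time or series cannot be told apart from one between the compounds. Without MSB 20 µM replicates 1, 3 and 4 the count was 886, 855 and 836, and without the 4 doubted libraries 6827. Under library totals 81.4% of these genes had the higher value for MSB and under RLE 55.9%, against 43.8% under TMM, and the median of all genes moved from -0.06 to 0.16.

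The response was higher with MSB for Efhb (4.34 ± 1.01; adjusted p = 0.00848), Kbtbd11 (2.90), Arrdc3 (2.35 ± 0.21; 1.75e-07), Vnn1, Zim1, C1qtnf7, Bmf, Dlg2, Ypel1 and Lck. It was lower with MSB for Il1rl1 (-3.86 ± 1.13; adjusted p = 0.0345), Ms4a2 (-3.66), St8sia1, Angptl4, Vat1l, Tnip3 (-3.06 ± 0.30; 1.08e-06), Eln (-3.04), Fxyd3, Ivl and Gdf6. Of 39 ATF4 genes 10 had the higher response with MSB and 1 the lower (camera adjusted p = 8.1e-11; 0.0773 with an estimated correlation). The mitochondrially encoded list, with 6 of 8 lower (1.11e-11), and the metallothionein list, with 2 of 6 lower (0.00269), were past the threshold with an estimated correlation (adjusted p = 0.0461 for both). Without the 4 doubted libraries these were 0.0817 and 0.0143, so the mitochondrial list no longer passed, while G2/M and S phase did (0.0492 for both). At the low doses edgeR's interaction called 0 genes, with 927 at an unadjusted p under 0.05; DESeq2 called 0 and voom 419, and 254 were called by edgeR without the 4 doubted libraries.

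**Figure D3:**
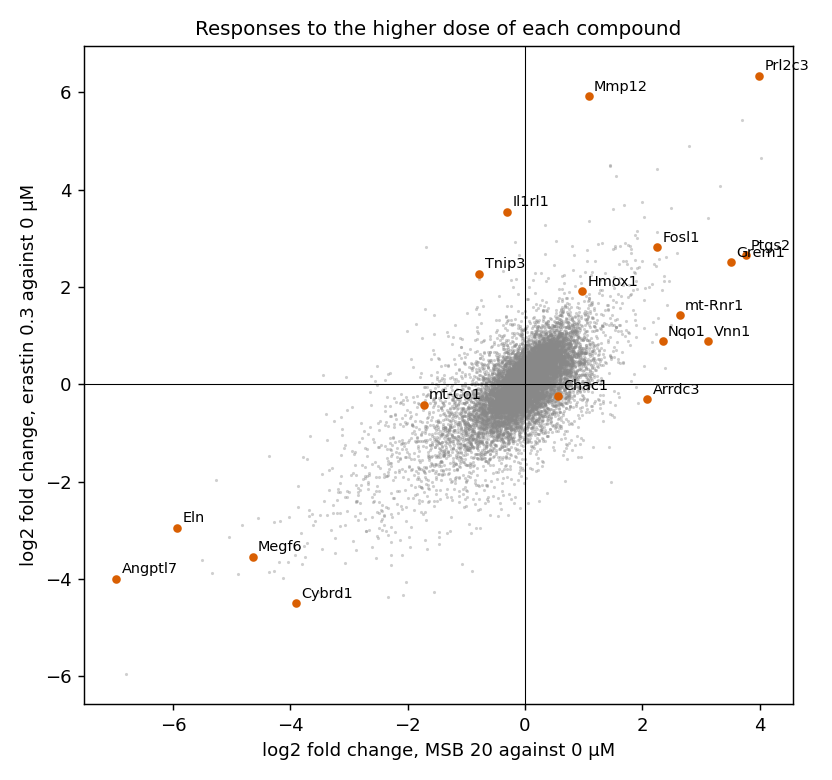
Log2 fold change of each gene with MSB at 20 µM (x axis) and erastin at 0.3 µM (y axis), each against its own 0 µM group; grey points are genes and orange points are labelled genes named in the text or its plots. The fold changes correlated with r = 0.698 across 14058 genes.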

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

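The tests of RNA from other cells, of a larger response to erastin and of the ratio of mitochondrial RNAs were chosen only after the results were seen, as were the fits without the doubted libraries.

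Among the 4 libraries of a group, a library stood apart when its gap to the nearest other took most of the group's range, by Dixon's 95% bound for 4 samples, which chance passes in about 1 in 20 groups. For the share of alignments on genes this was MSB 10 µM replicate 3, at 65.7%, and for the number of genes with a count MSB 20 µM replicate 2, with 6270. For the CPM of named genes it was MSB 20 µM replicate 2 at 109 genes, erastin 0.15 µM replicate 4 at 90 and erastin 0.3 µM replicate 2 at 15. The other libraries stood apart at 7 genes or fewer. MSB 0 µM replicates 1 to 4 stood apart at 1, 3, 7 and 2 genes, and MSB 10 µM replicates 1 and 3 at 2 and 4. Erastin 0 µM replicates 1 to 4 did so at 2, 3, 4 and 3 genes, 0.15 µM replicate 3 at 1, and 0.3 µM replicates 1, 3 and 4 at 4, 1 and 1. MSB 20 µM replicate 2 had 19799 counts, so its levels carry large counting error.

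Erastin 0.15 µM replicate 4 differed from replicates 1 to 3 of its group by more than the other libraries of that dose did. A large share of RNA from the 6 listed cell types is argued against. At most 20% of a list's members, 3 of 15 macrophage genes (Cd68, Csf1r and Mrc1), reached 5 CPM and 2 times the highest other library, where 50% was the bound. Cd14 at 18.6 CPM and Cd68 at 9.69 were the most abundant of that list. Cdh5, Grhl2 and Fabp4 of the endothelial, epithelial and adipocyte lists also rose this far. A small admixture or an unlisted cell type could not meet the bound, so the test does not exclude them. This library had 26717 genes with a count, and the highest other erastin library 23506. Transcript length accounts for 0.0182% of the variance of its deviation. A larger response to erastin may explain the pattern: over 9442 genes called at 0.3 µM without the low-yield libraries, its differences from controls had a slope of 1.31 on those of 0.3 µM replicates 1 and 3, against 0.138 to 0.152 for replicates 1 to 3 of its own group and 0.881 and 0.995 for 0.3 µM replicates 2 and 4. A 0.3 µM library under this label cannot be told apart from that: 786 genes lay over 2-fold outside the 0.3 µM libraries, above the bound set beforehand, which was 677 for 0.3 µM replicate 2, but by less than the spread of the 0.3 µM values (0, 2, 14 and 677), a condition added after this was seen.

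With MSB at 20 µM the mitochondrial rRNA genes were higher and the mitochondrial mRNAs tested in the main fit lower. Carry-over of ribosomal RNA, as far as 3 loci with rRNA sequence track it, is argued against as the whole cause. The rise of mt-Rnr1 was 2.65 before and 2.32 ± 0.08 after the level of these loci entered the fit. The genes called went from 9957 to 9464. Carry-over of mitochondrial rRNA that these loci do not follow was not tested, and mt-Rnr1 was also high in some erastin libraries, which received no MSB. Scaling of the libraries is argued against as well, since the log2 ratio of mt-Rnr1 to mt-Co1, which no scaling changes, differed by 4.34 between the group means, from -5.38 to -1.04, with no overlap of libraries. A change in mitochondrial RNA under MSB may stand behind the pattern, as a hypothesis found and tested on the same data. Reads shared with nuclear copies of these genes and differences in the selection of polyadenylated RNA were not tested.

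Ribosomal protein genes were higher with erastin at 0.3 µM (median 0.59), while without the low-yield libraries their median was 0.01. A bias by transcript length in replicate 2 is a candidate explanation: its deviation from replicates 1 and 3 had a slope of -0.49 on log2 exon length, where controls lay between -0.03 and 0.04, and removing length lowered the list's median deviation from 1.35 to 0.65. For replicate 4 the slope was -0.16 and the median went from 0.54 to 0.32, less than the fall set beforehand as the bound, so length there cannot be told apart from other causes. A biological effect of erastin on these genes stays open, with adjusted p = 0.607 without the low-yield libraries.

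The responses of the compounds differed by the interaction term at 1360 genes at the high doses, which were not matched between compounds. Among 100 drawn splits of the libraries, 2 gave as many, the real one included, and the other gave 4151. That split exchanged the MSB groups except for 1 library of each. The MSB response was thereby turned against that of erastin. Other splits mixed treated with control libraries, which adds the treatment effect to the spread. Neither kind shows what chance gives where both compounds act alike. The splits therefore do not settle whether chance gave this count. The values for named genes were 4.34 for Efhb, 2.90 for Kbtbd11, 2.35 for Arrdc3, 2.26 for Vnn1, 2.24 for Zim1, 2.23 for C1qtnf7, 2.15 for Bmf, 2.13 for Dlg2, 2.12 for Ypel1 and 2.10 for Lck. On the other side they were -2.83 for Gdf6, -2.92 for Ivl, -2.93 for Fxyd3, -3.04 for Eln, -3.06 for Tnip3, -3.22 for Vat1l, -3.29 for Angptl4, -3.32 for St8sia1, -3.66 for Ms4a2 and -3.86 for Il1rl1.

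By camera, 9 lists differed between the high-dose responses. Adjusted p was 8.1e-11 for ATF4, 1.11e-11 for mitochondrially encoded mRNAs, 9.77e-10 for G2/M, 1.2e-07 for hypoxia, 5.78e-07 for S phase, 9.51e-05 for heat shock, 0.000351 for matrix, 0.00269 for metallothioneins and 0.0398 for inflammatory genes. With an estimated correlation, the mitochondrial and metallothionein lists stayed past the threshold (adjusted p = 0.0461 for both). Without the doubted libraries these were 0.0817 and 0.0143, with G2/M and S phase at 0.0492 each, and by the preset correlation the inflammatory list no longer passed (0.0624). At the low doses 16 lists differed, though edgeR's interaction called 0 genes there, with 927 at an unadjusted p under 0.05 and 0 by DESeq2. Adjusted p was 2.01e-23 for G2/M, 7.51e-09 for heat shock and for immediate early genes, 1.25e-08 for NRF2 targets, 5.04e-08 for oxidative phosphorylation, 9.59e-08 for lysosome, 4.18e-07 for hypoxia and 1.54e-06 for ribosomal proteins. It was 0.00116 for mitochondrially encoded mRNAs, 0.0103 for the VPS34 list, 0.0171 for matrix, 0.02 for S phase, 0.0231 for autophagy, 0.0397 for inflammatory genes, 0.0434 for metallothioneins and 0.0437 for macrophage markers. Without the doubted libraries 5 of the 16 no longer passed: mitochondrially encoded mRNAs and macrophage markers (0.893 each), inflammatory genes (0.217), immediate early genes (0.0695) and autophagy (0.0575), and the matrix list changed direction (0.0296). None of the 16 passed with an estimated correlation, where the lowest was G2/M at 0.175, but G2/M was at 0.00533 without the doubted libraries.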

How the results depend on the processing

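Chosen only after the data were seen were voom with quality weights, fry, all fits without the near-empty, low-yield or doubted libraries, and the DESeq2 correlations over genes with an adjusted p. Except where construction shows it, the cause was not tested.

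Against 9792 genes for MSB 20 µM, DESeq2 called 3205, and against 9201 for MSB 20 against 10 µM it called 2519. Leaving out each library gave 9029 to 9957 and 8347 to 9401. Against 1334 for MSB 10 µM, DESeq2 called 5 and voom 2359, and leaving out each library gave 690 to 1842. With the near-empty library left out DESeq2 called 9485, 8837 and 1673 for these comparisons, so that library accounts for its lower counts.

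Against 3901 genes for erastin 0.3 µM, voom called 9837, edgeR without the low-yield libraries 9511, DESeq2 without them 8637, and edgeR with the deviating low-dose library out of the spread 6929; leaving out each library gave 2319 to 4256. Against 0 for erastin 0.15 µM by edgeR, with 823 at an unadjusted p under 0.05, DESeq2 called 2, voom 224, edgeR without the low-yield libraries 358 and DESeq2 without them 411; leaving out each library gave 0 to 2. Against 1337 for erastin 0.3 against 0.15 µM, no filter gave 825, 10 CPM in 4 libraries 838, DESeq2 2364, voom 8694, only the 2 groups 29, and fits without the low-yield libraries 8489 by edgeR and 7583 by DESeq2; leaving out each library gave 266 to 5472, the highest without 0.15 µM replicate 4.

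Against 1360 genes for the high-dose difference between compounds, no filter gave 814, 10 CPM in 4 libraries 831, DESeq2 480, voom 7711, and fits without the doubted libraries 6827 by edgeR and 6519 by DESeq2; leaving out each library gave 836 to 2018. Against 0 at the low doses, voom called 419 and fits without the doubted libraries 254 and 502; leaving out each library gave 0 to 4.

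The correlation between compounds (0.698) was 0.756 over genes at 10 CPM, 0.68 without the doubted libraries and 0.674 to 0.71 leaving out each library. With DESeq2's fold changes it was 0.242 over 26285 genes with a p-value, and 0.668 over 13285 with an adjusted p, a limit set after the first value was seen. Between the MSB doses (0.48) these were 0.587 at 10 CPM, 0.041 and 0.508 by DESeq2, and 0.445 to 0.493. Between the erastin doses (0.703), DESeq2 gave 0.505, the fit without the low-yield libraries 0.55, and leaving out each library 0.523 to 0.733.

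Whether replicate numbers pair the libraries is not settled. Of 24 same-numbered pairs, 5 had deviations correlated over 0.1, and 7 libraries correlated best with their own number. With 4 libraries to choose from, about 1 in 4 would do so at random, so this number is no sign of pairing. Between MSB 0 and 10 µM all these correlations were positive, at 0.059, 0.081, 0.367 and 0.112. Only replicate 3 of 0 µM correlated best with its own number there, while replicates 1, 2 and 4 correlated best with another. Replicate 3 was also highest in both groups on the loci with rRNA sequence (mean log2 CPM 9.03 and 9.05). Every other comparison of groups holds a doubted library, whose deviation can mask pairing. With the replicate number as a block, 535 genes were called for erastin 0.3 against 0.15 µM; no other count moved by over 1.5 times.

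For the 418 values of named genes, 7424 alternatives kept direction and side of the threshold, 326 fell short of it, 178 newly passed and 19 reversed. The near-empty library's depth of 19799 counts limits what its levels can show. For erastin 0.3 µM, Lpl was at -0.235 without the low-yield libraries and -0.222 by DESeq2 without them, Egfl7 at -0.43 by voom and -0.46 without them, and Gpx4 at -0.267, -0.287 and -0.273 in these 3 fits. For 0.3 against 0.15 µM, values by voom, without the low-yield libraries and by DESeq2 without them were 3.442, 3.547 and 3.567 for Acsbg1, 4.954, 4.892 and 4.922 for Prl2c3, and 3.919, 4.079 and 4.091 for Mmp10. Leaving out each library these ran from -0.949 to 3.332, -1.247 to 5.052 and -1.444 to 4.042, with the highest without 0.15 µM replicate 4.

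For the 217 values of lists, 3785 alternatives held, 265 fell short, 120 newly passed and 30 reversed. By fry, adjusted p after reversing was 0.000141 and 0.000339 for macrophage markers in MSB 20 against 0 and 10 µM. For erastin 0.3 µM, oxidative phosphorylation was at 0.0335 without the low-yield libraries and 0.168 by fry. For erastin 0.15 µM, the unfolded protein response was at 0.0326 by fry, matrix at 0.297 without the low-yield libraries, 0.646 by fry and 0.00857 to 0.583 leaving out each library, and G2/M at 0.296, 0.566 and 3.04e-05 to 0.262. For 0.3 against 0.15 µM, fry gave 0.0128 for matrix, 0.0357 for lysosome, 0.586 for oxidative phosphorylation, 4.62e-05 for p53 targets, 0.0077 for the vitamin K cycle and 0.864 for the VPS34 list. Without the low-yield libraries oxidative phosphorylation was at 0.203 and the VPS34 list at 0.565, and leaving out each library gave 0.00645 to 0.9 for matrix. For the high-dose difference, ribosomal proteins were at 0.0495 by library totals, 2.85e-09 without the doubted libraries, 0.00281 by fry and 4.5e-06 to 0.925 leaving out each library. For the low-dose difference, cholesterol synthesis was at 5.08e-09 without the doubted libraries, 0.0157 by fry and 2.53e-05 to 0.194 leaving out each library, and matrix at 0.0296, 0.382 and 0.000243 to 0.0444.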

Other observations

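The splits reported here were planned before the results were seen, while the voom counts beside them were added afterwards. Other splits of the libraries into the same group sizes were refitted. For MSB 20 against 0 µM, 1 of 35 splits, the real one, gave 9792 genes, and the highest other gave 4406. For MSB 10 against 0 µM it was 1 of 35, with 1334 and 1107, and for MSB 20 against 10 µM 1 of 35, with 9201 and 3804. A share of 1 in 35 is the smallest these splits can give, which makes chance an unlikely source of these counts without excluding it. The other splits mix treated with control libraries, which adds any treatment effect to the spread, so their counts do not measure what chance alone gives. For MSB 10 against 0 µM this holds less firmly. The other count of 1107 lies within the 690 to 1842 genes called when each library was left out. The splits do not address cultures or batches that follow the groups. The highest other split of MSB 20 against 0 µM exchanged the near-empty library with a control, a structure of the samples. That of MSB 10 against 0 µM exchanged MSB 0 µM replicate 3 with MSB 10 µM replicate 1.

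For erastin 0.3 against 0 µM, 1 of 35 splits, the real one, gave 3901 genes and every other gave 0. Chance is thereby an unlikely source, with the same limits as for the MSB counts. For 0.3 against 0.15 µM, 4 of 35 gave at least 1337, the highest other 3001, so chance is not excluded; the 3 larger splits exchanged 0.15 µM replicate 4 with a 0.3 µM library. For 0.15 against 0 µM edgeR called 0 genes (823 at an unadjusted p under 0.05; DESeq2 2, voom 224), as it did for the low-dose difference between compounds (927; DESeq2 0, voom 419). With 0 called, other splits could not give fewer and say nothing about chance; the fits without the doubted libraries were not split.

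The file of MSB 20 µM replicate 1 holds 3 further columns, which equal replicates 2, 3 and 4 of that group at every gene listed.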
